A study of Homo sapiens with 7 samples.

How the data were processed

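Single-cell RNA-seq libraries were made by 3 droplet methods from cells labelled GM12891, a human lymphoblastoid line. There were 2 inDrop libraries, 3 Drop-Seq libraries and 2 10X libraries, 7 in all. Per the labels, the replicates differ in cell input, day and batch, and no label says which libraries share a day or a culture. A check of sample identity found that 7 of 7 libraries did not match the labelled line, so the cells are called "labelled GM12891" throughout.

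The deposited files hold, per library, 1 table of read counts and 1 table of UMI counts (unique molecular identifiers, the number of distinct molecules) per gene symbol and cell barcode, with no normalization. Per the submitters' processing notes, reads were aligned with STAR to GRCh38. The program that counted reads, its annotation, its use of strand, its treatment of reads shared between genes and its rules for barcodes and UMIs are stated neither in the labels nor in those notes. The values show that each deposited table lists only genes with a mean count over 0.1 per barcode. A gene missing from a table is therefore unlisted, not 0, and the listing minimum corresponds to 25.2 and 26.5 CPM (counts scaled to a common library total) in the inDrop libraries, 10.7 to 12.5 in the Drop-Seq libraries and 3.60 and 3.65 in the 10X libraries. Of 9790 genes in any UMI table, 4398 were listed in all 7, and 8730 genes were listed in every read table. The 4398 genes held 98.0% and 97.8% of the UMIs of the inDrop libraries, 92.1%, 92.3% and 92.4% of those of the Drop-Seq libraries and 90.7% and 90.0% of those of the 10X libraries.

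All barcodes were used as deposited, 19630 in all, and 7, 4 and 4 barcodes of the Drop-Seq libraries had 0 UMIs. No doublet caller was run and the labels do not say whether doublets were removed. Leaving out the 5% of barcodes with the most UMIs was an alternative. The library was the replicate throughout, and no p-value was made from barcodes. The library totals ranged from 8174239 to 177417463 UMIs. Intervals of shares are 95% Wilson intervals and cover counting error only.

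Values per library were compared over the 3 methods by an exact permutation test over all 210 assignments of the 7 libraries to groups of 2, 3 and 2. The statistic was the sum of squares between groups of log2 values, and the test was one-sided on it. Its smallest possible p is 0.009524. Pairs of methods have no such test, since 2 against 2 libraries cannot go below a two-sided p of 0.3333 and 2 against 3 cannot go below 0.2. To compare genes per barcode and variation between barcodes at equal depth, each barcode was thinned without replacement to 3000 UMIs and shallower barcodes were left out. To compare UMIs at equal sequencing, barcodes with 32000 to 48000 reads were taken. A gene was called overdispersed when its variance over its mean across thinned barcodes exceeded 1.5, among genes with a thinned mean of at least 0.1. For gene lists, the variance over the mean of the summed UMIs per thinned barcode was divided by 1 minus the list's share. Variance over mean rises with the mean at equal relative variation, so it also reflects the level of a gene or list.

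UMI counts were summed per library and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the 4398 genes, all of which passed edgeR's filter on low counts. Scaling was by TMM, which sets each library's size from the ratios of most genes, and all 7 libraries entered 1 fit with 4 residual degrees of freedom. The p-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM are given with TMM-scaled library sizes as mean ± SD over libraries. These p-values measure differences against the spread between libraries of a method. Per the labels, that spread covers cell input, day and batch. No label says whether it covers a culture, so differences between cultures may coincide with those between methods. Libraries of the same method also differed beyond counting noise, with a chi-square per degree of freedom of 11.5 for inDrop, 8.49 to 33.1 for Drop-Seq and 97.5 for 10X. This value grows with total counts, so it does not rank the methods.

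Before the data were examined, 26 gene lists and 16 single genes were fixed, together with the tests and most alternatives. Of the lists, 22 had at least 5 genes tested. They were tested with limma's camera (limma 3.58.1), which compares a list's change with that of the other genes, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Its p-values were two-sided, and the adjustment was over the 66 tests of the 3 comparisons. The same test with the inter-gene correlation estimated from the data is given beside each call, and it called 0 of 66. The range of a list's adjusted p is over the alternatives other than that one. In each of the 21 called lists, every pair of libraries had a median change in the list's direction. This held for most lists that were not called too, so it does not set the called lists apart.

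The text names, per comparison, the 10 genes with the largest log2 fold change in each direction among those with an adjusted p under 0.05, a mean of at least 50 CPM in the higher method, no overlap of CPM between the libraries of both methods and a named symbol, leaving out those sex-linked genes that tell donors apart. It also names up to 4 members with the largest change of each called list, the 10 genes that varied most between barcodes, and the 16 fixed genes. Heavy-chain classes of barcodes, genes listed by 1 method only and the genes that separate those classes were chosen after the data were seen. Gene length and GC content came from GENCODE 29, which held 4246 of the 4398 symbols (96.5%). Positions are GRCh38, from GENCODE 29.

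Several named genes are uncertain because the treatment of shared reads is not stated. MTRNR2L12, MTRNR2L8 and MTRNR2L1 are nuclear copies that resemble the mitochondrial gene MT-RNR2. ATP5EP2 and FKBP1C resemble ATP5E and FKBP1A. IGLC2 resembles IGLC3, IGHA1 resembles IGHA2, CCDC74B resembles CCDC74A, the histone genes resemble each other, and many ribosomal protein genes have processed copies. MT-ATP8 overlaps MT-ATP6 and MT-ND4L overlaps MT-ND4. MIF-AS1 is annotated antisense, and without strand its reads cannot be told apart from those of an overlapping gene.

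The gene tests, list tests, thinning with variation between barcodes, and permutation test were tested on simulated data. With 200 of the 4398 genes changed, and the 14 S phase genes lowered 2-fold for the list test, 99% of those among the 200 changed 1.5-fold were recovered for inDrop against 10X, 99% for Drop-Seq against 10X and 98% for inDrop against Drop-Seq, and 100% of those changed 2-fold in each. Of the 4184 other genes, all unchanged, 0.191%, 0.167% and 0.382% were called, in the same order. In the data 83.3% to 84.9% of genes were called, so these rates do not test the scaling where most genes differ. The alternatives were DESeq2 1.42.0, other size factors (RLE), other filters on genes and barcodes, reads in place of UMIs, an equal number of barcodes, the replicate number as a block, and each library left out in turn. Those of the gene and list tests added after the data were seen were the genes of all read tables, UMIs corrected for collisions, genes of at least 100 CPM, the shallower 50% of barcodes, only barcodes with mostly IGHM or IGHD among their heavy-chain UMIs, the immunoglobulin genes left out, the 5% of barcodes with most UMIs left out, and replicates 1 and 2 without a block. For the lists alone, reads, an equal number of barcodes and the filter on UMIs and mitochondrial share were added then too. The other additions were the genes of all UMI tables or of the read table for values per barcode and variation of lists, inDrop against the other libraries together for the mitochondrial share, reads for the length and GC trends, and the genes of all read tables for the correlation of libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.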

Results

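Cells labelled GM12891, a line of B lymphocytes that divide without limit in culture, were profiled by 3 ways of capturing single cells in droplets, and the libraries compare how much RNA, and which RNA, each method recovers. The 2 inDrop libraries held 10179388 and 8174239 UMIs over 2565 and 2166 barcodes. The 3 Drop-Seq libraries held 17798499, 19782914 and 20645436 UMIs over 1912, 2366 and 2571 barcodes. The 2 10X libraries held 43511642 and 177417463 UMIs over 1567 and 6483 barcodes. The 7 UMI tables listed 4937 and 4944 genes for inDrop, 7154, 6950 and 6883 for Drop-Seq, and 9501 and 9474 for 10X.

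The methods differed in how many molecules each barcode gave. The median was 24485 ± 639 UMIs per barcode in 10X (SD, n = 2), 6893 ± 720 in Drop-Seq (SD, n = 3) and 3309 ± 201 in inDrop (SD, n = 2), a 7.40-fold range (one-sided exact permutation p = 0.009524, the smallest that 210 assignments can give). Listed genes per barcode followed the same order, with medians of 3720.0 ± 38.2, 2118 ± 126 and 1152 ± 6.36 (exact permutation p = 0.009524). With every barcode thinned to 3000 UMIs the order changed, with 1279 ± 6.66 listed genes in Drop-Seq, 1099 ± 35.4 in inDrop and 1055 ± 27.6 in 10X (exact permutation p = 0.01905). The lowest inDrop library and the highest 10X library were both at 1074, so these methods were not separated. Thinning kept 61.0% and 54.1% of inDrop barcodes, 95.9%, 95.9% and 98.02% of Drop-Seq barcodes and 99.9% and 99.9% of 10X barcodes. Without inDrop replicate 2 or without 10X replicate 1, the exact permutation p of genes at equal UMIs was 0.05. Without any Drop-Seq library, no comparison over the methods can go below 0.06667. The values at equal UMIs depend on how many genes each table lists. Thinned over only the genes of all 7 UMI tables, an alternative added after the data were seen, they were 1131.5 in Drop-Seq, 1056.5 in inDrop and 902 in 10X (exact permutation p = 0.009524).

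**Figure D1:**
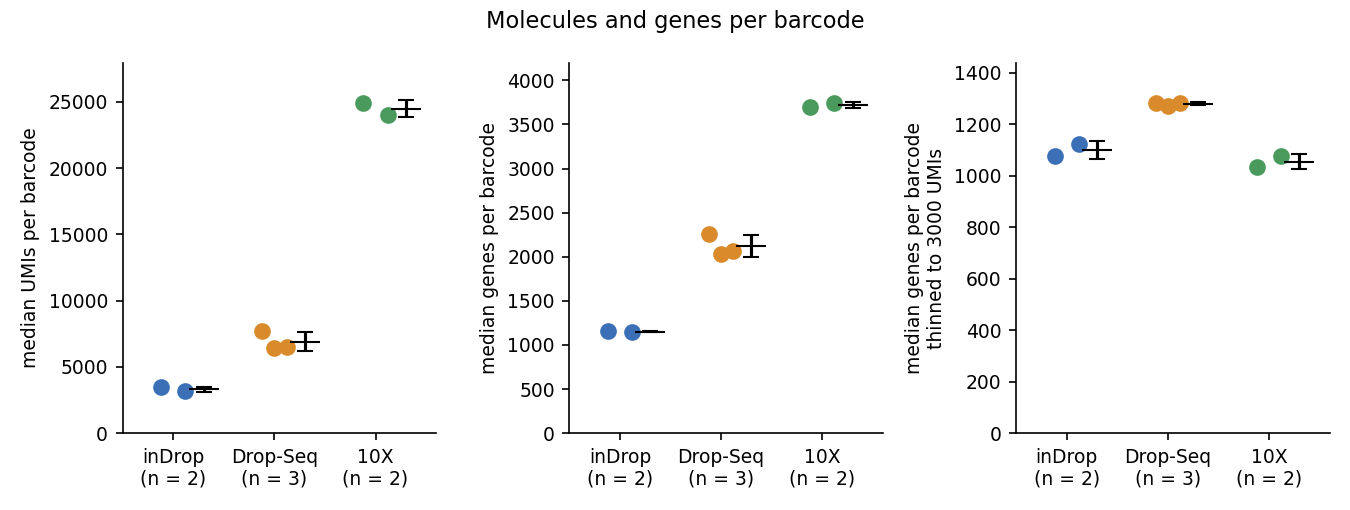
Median UMIs, median listed genes and median genes after thinning to 3000 UMIs, each per barcode on a linear axis from 0. Points are libraries, and the lines give the mean ± SD of inDrop (n = 2), Drop-Seq (n = 3) and 10X (n = 2); 10X stood highest at full depth with 24485 UMIs and 3720.0 genes, and Drop-Seq highest after thinning with 1279 genes.

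Sequencing depth did not run in parallel with molecules. Each UMI was read 9.61 ± 0.182 times in inDrop, 4.30 ± 0.451 times in Drop-Seq and 2.17 ± 0.124 times in 10X (exact permutation p = 0.009524). Among barcodes with 32000 to 48000 reads, the median was 18449 ± 903 UMIs in 10X, 8919 ± 870 in Drop-Seq and 3800 ± 37.1 in inDrop (exact permutation p = 0.009524).

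The share of RNA from the mitochondrial genome was 15.6% ± 0.347 of UMIs in inDrop, 3.38% ± 0.128 in Drop-Seq and 3.46% ± 0.377 in 10X. The 3-method test did not pass the threshold (one-sided exact permutation p = 0.09524), since Drop-Seq and 10X overlapped. It passed without 10X replicate 1 and without 10X replicate 2 (exact permutation p = 0.01667 each), with reads in place of UMIs (exact permutation p = 0.009524), and for inDrop against the other libraries together, a comparison added after the data were seen (exact permutation p = 0.04762). Without barcodes under 1000 UMIs or over 15% mitochondrial, a filter that removes high shares by design, the inDrop share was 9.45%, against 3.29% in Drop-Seq and 3.44% in 10X (exact permutation p = 0.05714). Genes of the cytosolic ribosome, which makes protein, took 31.8% ± 1.63 of UMIs in 10X, 26.9% ± 0.778 in Drop-Seq and 24.8% ± 1.51 in inDrop (exact permutation p = 0.009524). Only the place of 10X held in every alternative: without those barcodes Drop-Seq was lowest, with 26.995% against 28.4% in inDrop (exact permutation p = 0.04762), and with reads inDrop fell to 14.6%, against 25.8% in Drop-Seq and 31.3% in 10X (exact permutation p = 0.009524).

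**Figure D2:**
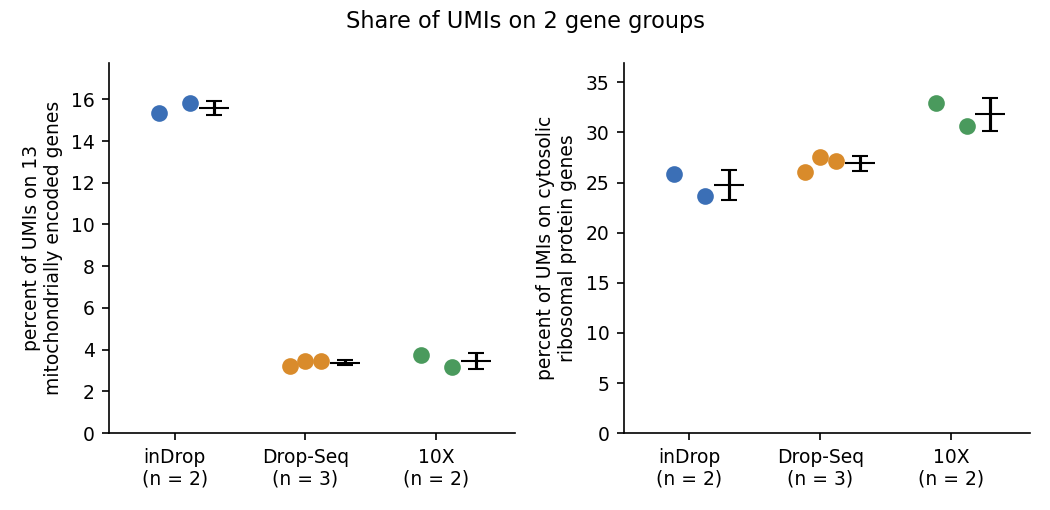
Percent of a library's UMIs on 13 mitochondrially encoded genes and on cytosolic ribosomal protein genes, on linear axes from 0. Points are libraries, and the lines give the mean ± SD; the inDrop libraries stood at 15.6% for the mitochondrial genes against 3.38% in Drop-Seq and 3.46% in 10X.

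The comparison of inDrop with 10X asked which transcripts the method with the fewest molecules per barcode gave relatively more or less of. Mitochondrial transcripts stood higher in inDrop and those for antibody secretion, ribosomes and the nuclear-encoded respiratory chain stood lower. MTRNR2L12, a nuclear copy of a mitochondrial gene at chromosome 3, 96617188 to 96618236, was at 4461 ± 177 CPM in inDrop and 13.7 ± 2.36 in 10X, a log2 fold change of 8.37 ± 0.25 (SE). JCHAIN, which joins the units of polymeric antibodies (chromosome 4, 70655541 to 70681817), was at 96.1 ± 35.2 CPM in inDrop and 3927 ± 63.6 in 10X, a log2 fold change of −5.35 ± 0.24 (SE). IGLC2, the constant part of a lambda light chain (chromosome 22, 22900976 to 22901437), was at 3810 ± 895 CPM in inDrop and 92472 ± 1011 in 10X, a log2 fold change of −4.60 ± 0.20 (SE). Over 4398 genes, edgeR's quasi-likelihood test called 3662 (83.3%) at a Benjamini-Hochberg adjusted p under 0.05, of which 1832 were higher in inDrop, 1830 were lower, and 1556 differed over 2-fold.

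After MTRNR2L12, the largest increases in inDrop against 10X were in MT-ATP8 (log2 fold change 6.98), MTRNR2L8 (5.63), NHSL2 (5.25), MAL (4.78), ATP5EP2 (4.002), the glucocorticoid-induced TSC22D3 (3.90), the interferon-inducible GBP4 (3.85), AUTS2 (3.72) and MT-ND3 (3.67). Beside JCHAIN and IGLC2, the largest decreases were in the antibody-secretion factor MZB1 (−4.61), the linker histone HIST1H1C (−4.61), the endoplasmic reticulum proteins SDF2L1 (−3.65), CRELD2 (−3.56) and PPIB (−3.25), the ferritin light chain FTL (−3.61), CYBA (−3.58) and the glycolytic enzyme ALDOA (−3.28). Among these 20 genes edgeR's adjusted p was at most 1.31e-09. That no inDrop library overlapped a 10X library was a condition of their choice.

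Of the gene lists, 9 of 22 were called for inDrop against 10X by camera. Of 13 mitochondrially encoded genes 12 were higher and 1 lower, all 13 called also when adjusted over the list alone, with a median log2 fold change of 1.95 (adjusted p = 5.996e-04; adjusted p = 0.679 with an estimated correlation). MT-ND4L rose by 2.96 and MT-ND1 by 2.15. Of 75 nuclear-encoded respiratory chain genes 3 were higher and 67 lower, 70 called when adjusted over the list alone, with a median of −1.12 (adjusted p = 5.641e-10; adjusted p = 0.432 with an estimated correlation). NDUFB10 (−2.95), NDUFB7 (−2.91) and ATP5D (−2.81) fell most. Of 83 cytosolic ribosomal protein genes 3 were higher and 70 lower, 73 called when adjusted over the list alone, with a median of −1.03 (adjusted p = 1.307e-08; adjusted p = 0.703 with an estimated correlation). RPS15 (−2.29) and RPL19 (−2.16) fell most. Of 21 plasma cell and secretory genes 2 were higher and 18 lower, 20 called when adjusted over the list alone, with a median of −1.57 (adjusted p = 1.812e-04; adjusted p = 0.625 with an estimated correlation). Beside JCHAIN and MZB1, the surface receptors CD27 (−2.69) and TNFRSF17 (−2.43) fell most. With only barcodes led by IGHM or IGHD, that list's median was −0.93 and its adjusted p 0.0879 (range over the alternatives 1.674e-06 to 0.0879).

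Lists of the cell cycle and the proteasome were lower in inDrop than in 10X, and the immediate early and NF-kB target lists were higher. Of 28 G2 and M phase genes 2 were higher and 22 lower, 24 called when adjusted over the list alone, with a median log2 fold change of −0.79 (camera, adjusted p = 9.41e-04; adjusted p = 0.679 with an estimated correlation). UBE2C (−2.21), TUBB4B (−2.11) and the proliferation marker MKI67 (−1.88) fell most. Of 14 S phase genes 2 were higher and 10 lower, 12 called when adjusted over the list alone, with a median of −1.03 (adjusted p = 0.0268; adjusted p = 0.625 with an estimated correlation), led by SLBP (−2.27) and RRM2 (−2.24). Of 30 proteasome genes 2 were higher and 24 lower, 26 called when adjusted over the list alone, with a median of −0.77 (adjusted p = 3.442e-04; adjusted p = 0.731 with an estimated correlation), led by PSMC5 (−2.44) and PSMB3 (−2.37). Without TMM, the share of thinned UMIs on proteasome genes overlapped between the methods. It was 0.330% and 0.358% in inDrop and 0.344% and 0.427% in 10X. Of 17 immediate early genes, which respond within minutes to a stimulus, 14 were higher and 2 lower, 16 called when adjusted over the list alone, with a median of 0.66 (adjusted p = 0.0336; adjusted p = 0.620 with an estimated correlation), led by RGS1 (2.72), KLF6 (2.41) and, in the other direction, BTG2 (−2.02). Of 36 NF-kB target genes 22 were higher and 6 lower, 28 called when adjusted over the list alone, with a median of 0.35 (adjusted p = 0.0441; adjusted p = 0.679 with an estimated correlation), led by STAT5A (2.54), CD80 (2.52) and EBI3 (2.51).

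Some of these list calls ended under alternatives. With reads in place of UMIs, camera gave an adjusted p of 0.0675 for G2 and M phase (range over the alternatives 4.288e-04 to 0.131), 0.194 for immediate early genes (0.0102 to 0.194) and 0.573 for NF-kB targets (0.001558 to 0.573), with medians of −0.48, 0.66 and 0.37. Over the genes of every read table the adjusted p were 0.127, 0.127 and 0.363 and the medians −0.39, 0.75 and 0.45. The SD of log2 fold changes over all genes was 1.63 and 1.60 in these read fits, against 1.13 in UMIs. In the shallower 50% of barcodes the median of G2 and M phase turned to 0.38 (adjusted p = 0.131), that of S phase was −0.20 (adjusted p = 0.791; range 0.005232 to 0.791) and that of immediate early genes 0.55 (adjusted p = 0.0732). Over genes of at least 100 CPM the medians of G2 and M phase, S phase and proteasome were −0.42, −0.91 and −0.35 (adjusted p = 0.0569, 0.0767 and 0.111, the last from 4.005e-05 to 0.111). Without barcodes under 1000 UMIs or over 15% mitochondrial, they were 0.50 for immediate early genes (adjusted p = 0.0553) and 0.28 for NF-kB targets (adjusted p = 0.0893). For NF-kB targets the median was also 0.35 without ribosomal protein and mitochondrially encoded genes (adjusted p = 0.0598), 0.47 with only barcodes led by IGHM or IGHD (adjusted p = 0.0880) and 0.37 without 10X replicate 1 (adjusted p = 0.0521). Scaling on genes of at least 100 CPM moved all genes of inDrop against 10X by 0.51 log2 and left the sign of each called list's median as it was.

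The 13 other lists did not pass for inDrop against 10X. Camera's adjusted p ran from 0.219 for glycolysis and hypoxia (median log2 fold change −0.52) to 0.955 for nuclear long noncoding RNAs (0.18), with 0.227 for zinc finger transcription factors, 0.245 for heat shock, 0.313 for the interferon response, 0.333 for cholesterol synthesis, 0.370 for B cell identity, 0.546 for replication-dependent histones, 0.574 for p53 targets and apoptosis, 0.654 for MHC class II, 0.666 for unfolded protein and amino acid stress, 0.673 for MHC class I and 0.706 for immunoglobulins. The test and the median differed in sign for nuclear long noncoding RNAs.

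Of the 16 genes fixed beforehand, 6 were higher in inDrop than in 10X, 9 were lower and ACTB did not pass (log2 fold change 0.27, edgeR's adjusted p = 0.0579). The higher ones were IGHM (1.02), MT-CO1 (0.90), HLA-DRA (0.72), MS4A1 (0.63), EEF1A1 (0.58) and CD79A (0.33). The lower ones were FTL (−3.61), MALAT1 (−2.99), TMSB10 (−2.33), TMSB4X (−1.96), MKI67 (−1.88), GAPDH (−1.77), FTH1 (−1.22), CD74 (−0.46) and B2M (−0.45). EEF1A1, CD79A and IGHM had the opposite sign with reads in place of UMIs, B2M and IGHM with only barcodes led by IGHM or IGHD, CD74 and B2M over genes of at least 100 CPM, and CD79A in the shallower 50% of barcodes. Scaling on genes of at least 100 CPM moved all genes by 0.51 log2, and the barcodes led by IGHM or IGHD were chosen by IGHM itself.

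Drop-Seq was compared with 10X to show which transcripts changed between the methods with most molecules per barcode. Ribosomal protein genes, MHC class II genes, which present antigen to T cells, and secretory genes stood lower in Drop-Seq. LTB, a lymphocyte cytokine subunit (chromosome 6, 31580525 to 31582522), was at 18.1 ± 1.72 CPM in Drop-Seq and 263 ± 20.97 in 10X, a log2 fold change of −3.86 ± 0.10 (SE). MT-ATP8, a subunit of the mitochondrial ATP synthase, was at 1469 ± 207 CPM in Drop-Seq and 13.7 ± 4.05 in 10X, a log2 fold change of 6.78 ± 0.22 (SE). IGHM, the heavy chain of IgM (chromosome 14, 105851705 to 105856218), was at 13206 ± 805 CPM in Drop-Seq and 2548 ± 467 in 10X, a log2 fold change of 2.37 ± 0.17 (SE). With only barcodes led by IGHM or IGHD, which are chosen by that gene, its log2 fold change was −0.08. Of 4398 genes edgeR's quasi-likelihood test called 3732 (84.9%) at a Benjamini-Hochberg adjusted p under 0.05, of which 1892 were higher in Drop-Seq, 1840 were lower, and 1407 differed over 2-fold.

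After MT-ATP8, the largest increases in Drop-Seq against 10X were in MTRNR2L12 (log2 fold change 3.55), CPT1A of fatty acid import into mitochondria (3.33), SEPT10 (3.33), PIK3R5 (3.20), the interleukin 18 receptor IL18R1 (3.16), RASSF4 (2.98), LARP7 (2.68), CCDC74B (2.62) and the receptor kinase EPHB1 (2.57). After LTB, the largest decreases were in JCHAIN (−3.84), FKBP1C (−3.81), CD27 (−3.22), STAG3 (−3.07), the protease CTSZ (−3.06), the interferon-induced ISG15 (−2.93), APH1A (−2.89), IGLC2 (−2.86) and GPSM3 (−2.80). Among these 20 genes edgeR's adjusted p was at most 1.506e-10. That no Drop-Seq library overlapped a 10X library was a condition of their choice.

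Camera called 3 of 22 lists for Drop-Seq against 10X. Of 83 cytosolic ribosomal protein genes 6 were higher and 63 lower, 69 called when adjusted over the list alone, with a median log2 fold change of −0.68 (adjusted p = 1.987e-06; adjusted p = 0.764 with an estimated correlation), led by RPL23A (−2.35) and RPL29 (−2.24). Of 9 MHC class II genes 0 were higher and 9 lower, 9 called when adjusted over the list alone, with a median of −1.15 (adjusted p = 0.001767; adjusted p = 0.679 with an estimated correlation). HLA-DPB1 (−1.78), CD74 (−1.75) and HLA-DMA (−1.69) fell most. Of 21 plasma cell and secretory genes 2 were higher and 15 lower, 17 called when adjusted over the list alone, with a median of −0.91 (adjusted p = 0.0022; adjusted p = 0.679 with an estimated correlation). Beside JCHAIN and CD27, MZB1 (−2.22) and the plasma cell transcription factor XBP1 (−2.18) fell most. With only barcodes led by IGHM or IGHD, the medians were −0.37 for MHC class II (adjusted p = 0.0941; range over the alternatives 3.601e-04 to 0.0941) and −0.68 for plasma cell and secretory genes (adjusted p = 0.158; range 3.455e-05 to 0.158).

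The 19 other lists did not pass for Drop-Seq against 10X. Camera's adjusted p was 0.0612 for B cell identity (median log2 fold change −0.70) and for immediate early genes (−1.06), 0.157 for the interferon response, 0.165 for G2 and M phase (0.74), 0.171 for glycolysis and hypoxia, 0.198 for S phase (0.66), 0.203 for the nuclear-encoded respiratory chain, 0.271 for MHC class I, 0.382 for heat shock, 0.385 for unfolded protein and amino acid stress, 0.565 for cholesterol synthesis, 0.576 for the proteasome, 0.609 for nuclear long noncoding RNAs, 0.794 for immunoglobulins and 0.933 for mitochondrially encoded genes (−0.44). It was 0.955 for NF-kB targets, replication-dependent histones, p53 targets and apoptosis, and zinc finger transcription factors. The test, the mean or the median differed in sign for mitochondrially encoded genes, NF-kB targets, replication-dependent histones and zinc finger transcription factors.

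Of the fixed genes, IGHM, MS4A1 (log2 fold change 1.47) and MKI67 (0.78) were higher in Drop-Seq than in 10X, and TMSB10 did not pass (−0.17, edgeR's adjusted p = 0.175). The other 12 were lower, from FTL (−1.82), CD74 (−1.75), TMSB4X (−1.71), ACTB (−1.71), B2M (−1.53), FTH1 (−1.30), CD79A (−1.29) and MALAT1 (−1.14) to EEF1A1 (−0.96), MT-CO1 (−0.96), GAPDH (−0.88) and HLA-DRA (−0.85).

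The comparison of inDrop with Drop-Seq asked which transcripts differed between the methods with fewer molecules per barcode. Mitochondrially encoded, immediate early, B cell identity, NF-kB target and interferon response genes stood higher in inDrop, and genes of the cell cycle, the proteasome and the nuclear-encoded respiratory chain stood lower. DUSP5, a phosphatase that limits ERK signalling (chromosome 10, 110497838 to 110511544), was at 211 ± 26.5 CPM in inDrop and 14.1 ± 0.825 in Drop-Seq, a log2 fold change of 3.90 ± 0.10 (SE). NASP, a histone chaperone of S phase, was at 45.3 ± 3.22 CPM in inDrop and 554 ± 22.7 in Drop-Seq, a log2 fold change of −3.61 ± 0.11 (SE). MTRNR2L12 was at 158 ± 40.6 CPM in Drop-Seq, a log2 fold change of 4.82 ± 0.18 (SE) in inDrop against it. Over the 4398 genes, edgeR's quasi-likelihood test called 3735 (84.9%) at a Benjamini-Hochberg adjusted p under 0.05, of which 1869 were higher in inDrop, 1866 were lower, and 1591 differed over 2-fold.

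The other largest increases in inDrop against Drop-Seq were in NHSL2 (log2 fold change 4.11), FKBP1C (3.82), the kinase PIM2 (3.73), the serine and glycine enzymes SHMT2 (3.55) and PHGDH (3.32), the interferon-induced IFI44L (3.44), the glutamine transporter SLC1A5 (3.43) and EDEM1 of protein quality control (3.34). Beside NASP, the largest decreases were in HIST1H1C (−3.83), the fatty acid binding protein FABP5 (−3.80), the splicing proteins PNN (−3.53) and RBM25 (−2.91), HIST2H2AA3 (−3.31), CRELD2 (−3.23), PPIB (−3.22), the replication inhibitor GMNN (−3.08) and the nucleolar NOP56 (−2.98). Among these 20 genes edgeR's adjusted p was at most 2.987e-12. That no inDrop library overlapped a Drop-Seq library was a condition of their choice.

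For inDrop against Drop-Seq camera called 9 of 22 lists, of which 5 stood higher. Of 13 mitochondrially encoded genes 11 were higher and 1 lower, 12 called when adjusted over the list alone, with a median log2 fold change of 2.00 (adjusted p = 0.0022; adjusted p = 0.679 with an estimated correlation). MT-ND3 (3.00) and MT-ND4 (3.00) rose most and MT-ND6 (−2.53) was the lower one. Of 17 immediate early genes 14 were higher and 0 lower, 14 called when adjusted over the list alone, with a median of 1.27 (adjusted p = 3.796e-04; adjusted p = 0.432 with an estimated correlation). Beside DUSP5, JUNB (2.74) and DUSP2 (2.25) rose most. Of 22 B cell identity genes 16 were higher and 4 lower, 20 called when adjusted over the list alone, with a median of 0.73 (adjusted p = 0.0139; adjusted p = 0.432 with an estimated correlation), led by CD37 (2.90), CD22 (2.88) and the transcription factors SPIB (2.73) and EBF1 (2.28). Of 36 NF-kB targets 26 were higher and 7 lower, 33 called when adjusted over the list alone, with a median of 0.73 (adjusted p = 0.003288; adjusted p = 0.679 with an estimated correlation), led by EBI3 (2.13) and CD40 (2.10). Of 27 interferon response genes 18 were higher and 5 lower, 23 called when adjusted over the list alone, with a median of 0.58 (adjusted p = 0.0141; adjusted p = 0.625 with an estimated correlation). Beside IFI44L, IFITM1 (3.03) and IRF7 (2.16) rose most. With reads in place of UMIs, the adjusted p was 0.210 for B cell identity (range over the alternatives 0.005655 to 0.210), 0.182 for NF-kB targets (0.002219 to 0.182) and 0.182 for the interferon response (0.002467 to 0.182), with medians of 0.59, 0.76 and 0.77. Over the genes of every read table the adjusted p were 0.182, 0.127 and 0.127 and the medians 0.64, 0.80 and 0.81. The SD of log2 fold changes over all genes was 1.53 and 1.56 in these read fits, against 1.09 in UMIs.

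The other 4 called lists stood lower in inDrop than in Drop-Seq. Of 28 G2 and M phase genes 2 were higher and 23 lower, 25 called when adjusted over the list alone, with a median log2 fold change of −1.36 (camera, adjusted p = 7.422e-05; adjusted p = 0.679 with an estimated correlation), led by MKI67 (−2.65) and SMC4 (−2.29). Of 14 S phase genes 1 was higher and 13 lower, 14 called when adjusted over the list alone, with a median of −1.34 (adjusted p = 3.796e-04; adjusted p = 0.432 with an estimated correlation). Beside NASP and GMNN, HELLS (−2.63) fell most. Of 30 proteasome genes 0 were higher and 23 lower, 23 called when adjusted over the list alone, with a median of −1.20 (adjusted p = 1.812e-04; adjusted p = 0.715 with an estimated correlation), led by PSMA7 (−2.55) and PSMC1 (−2.53). Of 75 nuclear-encoded respiratory chain genes 5 were higher and 59 lower, 64 called when adjusted over the list alone, with a median of −0.995 (adjusted p = 7.416e-08; adjusted p = 0.432 with an estimated correlation), led by NDUFB10 (−2.48) and NDUFB6 (−2.36). Scaling on genes of at least 100 CPM moved all genes of this comparison by 0.50 log2 and left the sign of each called list's median as it was.

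The 13 other lists did not pass for inDrop against Drop-Seq. Camera's adjusted p was 0.0612 for MHC class II (median log2 fold change 1.09), 0.121 for cytosolic ribosomal proteins (−0.30), 0.143 for heat shock (−0.77), 0.203 for immunoglobulins (−1.36), 0.219 for zinc finger transcription factors, 0.271 for plasma cell and secretory genes (−0.53), 0.448 for replication-dependent histones, 0.531 for unfolded protein and amino acid stress, 0.729 for MHC class I, 0.744 for glycolysis and hypoxia, 0.775 for cholesterol synthesis, 0.783 for nuclear long noncoding RNAs and 0.800 for p53 targets and apoptosis. Of the fixed genes, ACTB (1.98), MT-CO1 (1.86), CD79A (1.62), HLA-DRA (1.57), EEF1A1 (1.54), CD74 (1.29) and B2M (1.08) were higher in inDrop. MKI67, TMSB10 (−2.15), MALAT1 (−1.85), FTL (−1.79), IGHM (−1.36), GAPDH (−0.89) and MS4A1 (−0.83) were lower. TMSB4X (−0.25, edgeR's adjusted p = 0.0819) and FTH1 (0.08, edgeR's adjusted p = 0.506) did not pass.

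**Figure D3:**
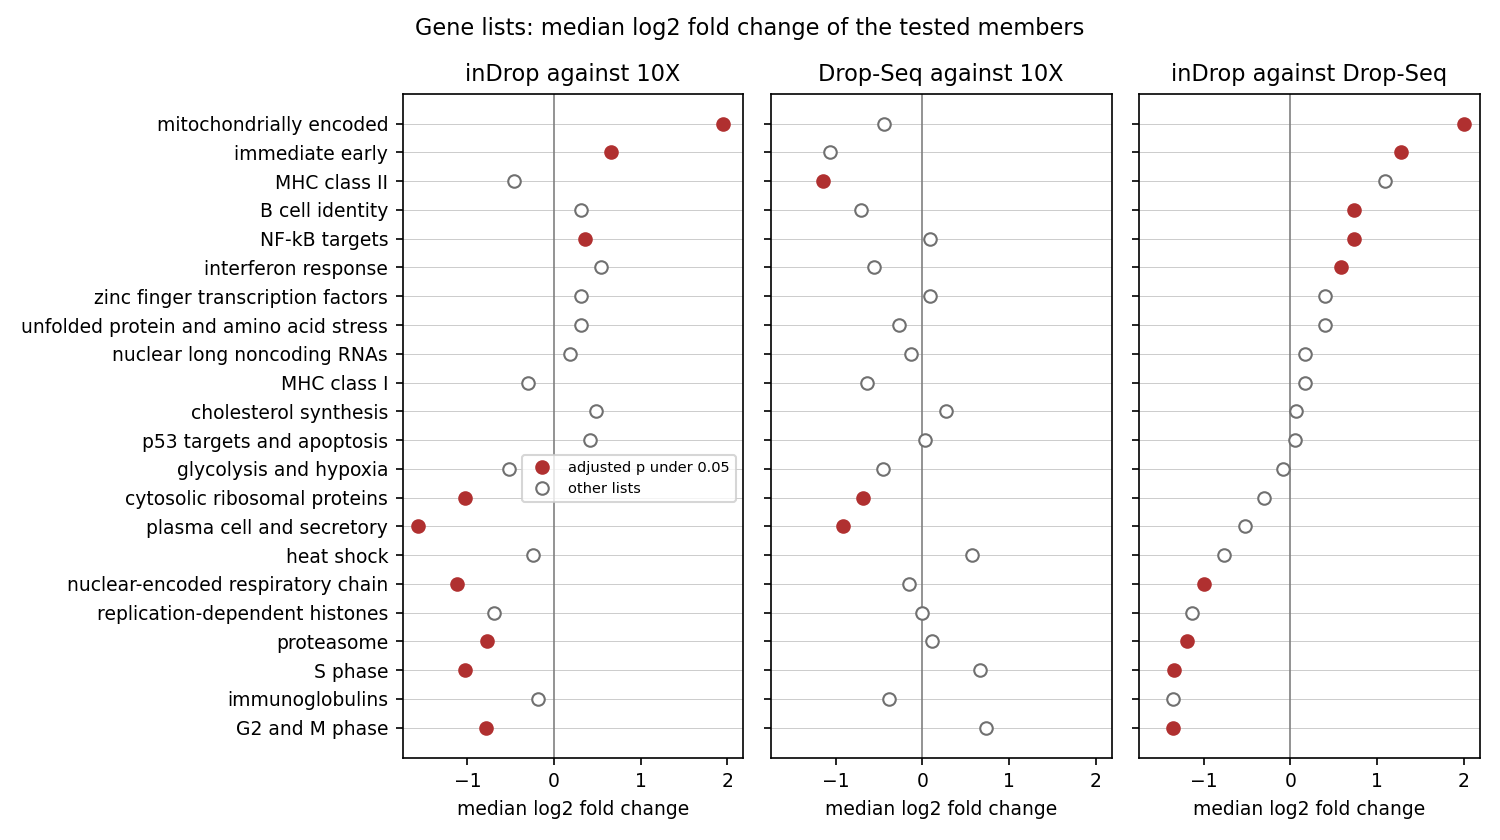
Median log2 fold change of the tested members of 22 gene lists in each comparison, on linear axes. Filled circles are lists with an adjusted p under 0.05 by camera with the preset correlation and open circles the others; mitochondrially encoded genes stood at 1.95 and 2.00 in inDrop against 10X and against Drop-Seq, and at −0.44, not called, in Drop-Seq against 10X.

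Markers of other cell types were few. Of the lists for T and NK cells, monocytes and dendritic cells, fibroblasts and epithelium, and erythroid cells and platelets, 2, 2, 1 and 0 genes were listed in all libraries, too few to test. The summed level of the T and NK cell genes was 83.8 ± 9.74 CPM in inDrop, 48.7 ± 1.92 in Drop-Seq and 116 ± 3.88 in 10X. That of the monocyte and dendritic cell genes was 189.8 ± 1.15, 162 ± 0.566 and 190.9 ± 12.7 CPM, and that of the fibroblast and epithelial gene was 24.8 ± 0.721, 17.7 ± 1.07 and 18.1 ± 2.56 CPM.

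Antibody genes separated the libraries further, which was examined after the data were seen. IGHA1, the heavy chain of IgA (chromosome 14, 105703995 to 105708665), gave 425 ± 68.7 UMIs per barcode in 10X (SD, n = 2) and was listed in no Drop-Seq or inDrop table, which makes its CPM in 10X at least 1088-fold higher than in Drop-Seq and at least 511.5-fold higher than in inDrop. IGHM gave 42.9 and 56.5 UMIs per barcode in the 10X libraries and 115 ± 5.16 in Drop-Seq. IgA led the heavy-chain UMIs of 79.0% (Wilson 95% interval 76.9 to 81.0) and 79.2% (78.2 to 80.1) of 10X barcodes, where a class led with at least 5 UMIs and 70% of them. IgM or IgD led 13.98% (12.3 to 15.8) and 12.7% (12.0 to 13.6) of 10X barcodes, and 95.1% (94.0 to 96.0), 97.2% (96.5 to 97.8) and 97.9% (97.2 to 98.3) of Drop-Seq barcodes. In inDrop IgM or IgD led 48.5% (46.5 to 50.4) and 48.1% (46.0 to 50.2), and the other 51.5% and 51.9% had under 5 heavy-chain UMIs. The UMI tables listed 2 of the class genes in inDrop (IGHM and IGHD), 3 in Drop-Seq (with IGHG1) and 7 in 10X. No other class could therefore lead in inDrop, and IgA could not lead in Drop-Seq. After thinning to 3000 UMIs, IgA led 68.4% and 72.7% of 10X barcodes, and IgM or IgD led 11.9% and 12.1% in 10X, 86.2%, 91.9% and 91.7% in Drop-Seq and 43.6% and 46.0% in inDrop. IgG led 3.06% (2.32 to 4.04) and 3.12% (2.72 to 3.57) of 10X barcodes, and 2.999% (2.26 to 3.97) and 4.94% (4.43 to 5.49) had no class at 70%. Barcodes of 10X led by IgM or IgD held 277 and 620.0 CPM of IGHA1, against 17730 and 22620 in those led by IgA.

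**Figure D4:**
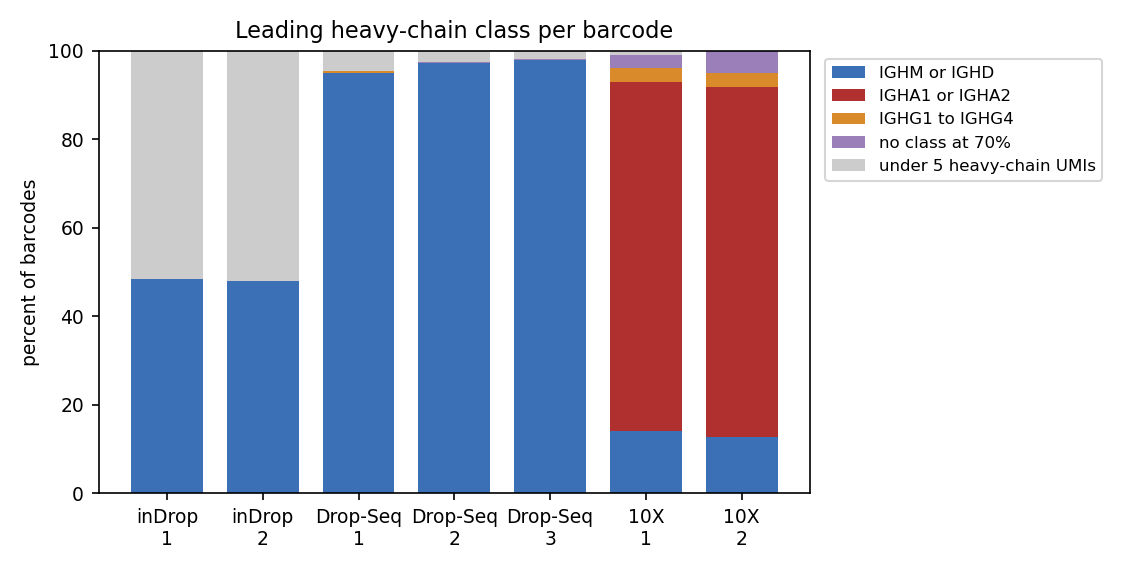
Percent of each library's barcodes by the heavy-chain class that leads their heavy-chain UMIs, stacked to 100. IgA led 79.0% and 79.2% in the 10X libraries, and in Drop-Seq and inDrop each class above 1% was IgM or IgD or had under 5 heavy-chain UMIs. No IgA gene was listed in Drop-Seq or inDrop, where IgA could not lead.

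Longer genes stood higher in inDrop and Drop-Seq than in 10X. Across 4246 genes, which are not independent replicates, Spearman's correlation of log2 fold change with gene model length was 0.451 for inDrop against 10X (0.426 to 0.470 over the 4 library pairs), 0.351 for Drop-Seq against 10X and 0.142 for inDrop against Drop-Seq. Genes in the lowest quartile of length, under 2209 nucleotides, had a median log2 fold change of −0.76 for inDrop against 10X and those in the highest, over 5537 nucleotides, of 0.49. For Drop-Seq against 10X these medians were −0.52 and 0.42, and for inDrop against Drop-Seq −0.24 and 0.19. With GC content the correlations were −0.161, −0.305 and 0.108 in the same order, and the last was −0.0447 with reads in place of UMIs.

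Libraries of the same method resembled each other more than those of other methods. Across the 4398 genes, the Spearman correlation of log2 CPM averaged 0.992 over the 5 pairs within a method (0.987 to 0.997) and 0.664 over the 16 pairs between methods (0.595 to 0.754), a difference of 0.328 (one-sided exact permutation p = 0.009524). The mean was 0.749 between Drop-Seq and 10X, 0.626 between inDrop and 10X and 0.605 between inDrop and Drop-Seq.

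Which genes varied most between barcodes was ranked over all libraries together, although the values differed between methods. At 3000 UMIs, the median over the 7 libraries of variance over mean was 90.01 for IGLC2, 66.2 for IGHM, 19.7 for the nuclear RNA MALAT1, 13.5 for ACTB, 12.4 for TMSB4X, 10.1 for HIST1H4C, 10.1 for JCHAIN, 8.33 for MT-CO3, 8.32 for the chemokine CCL3 and 8.14 for MT-CO1, out of 995 genes with a mean of at least 0.2 in every library. The share of overdispersed genes was 11.5% ± 0.765 in 10X, 9.45% ± 0.774 in inDrop and 6.92% ± 1.09 in Drop-Seq (one-sided exact permutation p = 0.02857). Without inDrop replicate 2, 10X replicate 1 or 10X replicate 2, that exact permutation p was 0.06667, 0.1333 and 0.05.

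Of 22 gene lists, 13 differed between the methods in the variance over mean of their summed UMIs per barcode. Exact permutation tests were used, with Benjamini-Hochberg over the lists. Since this value rises with a list's mean, it does not compare relative variation. Thinned S phase means, for example, were 10.3 to 10.7 UMIs in Drop-Seq against 2.14 and 2.51 in inDrop. The members listed differed between the methods, and with only the genes of all 7 UMI tables, an alternative added after the data were seen, 9 of the 22 lists passed. Plasma cell and secretory genes stood highest in 10X (exact permutation p = 0.009524, adjusted p = 0.0210). Their variance over mean was 28.3 ± 1.28 in 10X, 9.06 ± 0.730 in Drop-Seq and 5.49 ± 1.24 in inDrop. Their thinned means were 38.5 and 39.7 UMIs in 10X, 25.7 to 28.5 in Drop-Seq and 14.3 and 14.1 in inDrop. MHC class II (19.3 in 10X), MHC class I (11.04), glycolysis and hypoxia (14.7), NF-kB targets (11.5), the interferon response (8.06), proteasome (3.17) and cytosolic ribosomal proteins (103) were also highest in 10X, with the same exact p. Unfolded protein and amino acid stress genes were highest in Drop-Seq (9.66), with the same exact p. The 4 lists that passed only with all listed members were S phase, with the same exact p (6.92 in Drop-Seq from 40 or 41 genes, 3.35 in inDrop from 14 or 15), cholesterol synthesis and p53 targets and apoptosis (adjusted exact p = 0.0349) and immediate early genes (0.0484). Over the 14 S phase genes of all 7 UMI tables the values were 4.25 in Drop-Seq, 3.33 in 10X and 3.30 in inDrop (exact permutation p = 0.02857, adjusted p = 0.0571). The 9 others did not pass, with adjusted exact p of 0.0748 for the nuclear-encoded respiratory chain, 0.0838 for mitochondrially encoded genes, 0.0917 for B cell identity, 0.0986 for immunoglobulins, 0.128 for nuclear long noncoding RNAs, 0.154 for replication-dependent histones, 0.241 for G2 and M phase, 0.359 for zinc finger transcription factors and 0.391 for heat shock. The number that passed was 8 without inDrop replicate 1 and without 10X replicate 2, and 0 without any of the Drop-Seq libraries, where no list can pass.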

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

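The tests of the listing minimum and of failed capture for IGHA1, and the 3 tests on mitochondrial transcripts, were chosen only after the results were seen. The design gives no group other than the method, so no biological explanation was tested apart from it.

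Genes in the UMI tables of every library of 1 method and of no other library stood out, because no comparison of UMIs between methods used them. In 10X these were IGHA1 at 425 UMIs per barcode, IGHA2 at 37.3 and TCL1A, a lymphocyte signalling gene, at 4.51 (n = 2). In inDrop they were ACKR3 at 0.606 UMIs per barcode, MTRNR2L1 at 0.352 and ASS1 at 0.252 (n = 2). In Drop-Seq they were ENAM at 0.820, SNX32 at 0.501 and MIF-AS1 at 0.419, the last uncertain because the use of strand is not stated (n = 3). These are the 3 of each method with the highest CPM relative to the listing minimum of the others. Their lowest ratio to that minimum was 511.5 for IGHA1 and 3.33 for ENAM, but only 1.67 for MIF-AS1 and 1.47 for SNX32. In the read tables, TCL1A was listed for all 5 inDrop and Drop-Seq libraries (0.194 to 0.307 reads per barcode, against 10.2 and 10.4 in 10X), MIF-AS1 for both 10X libraries and ENAM for 1 of them, and the 6 other genes for no library of the other methods.

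IGHA1 was among the most abundant transcripts of both 10X libraries and was listed in no Drop-Seq or inDrop library. The listing minimum alone is excluded, since at its lowest 10X CPM it would have given at least 51.2 UMIs per barcode in every other library, far over 0.1. For Drop-Seq, 2 values argue against failed capture of IGHA1 from the same mix of cells. IGHM stood at least 4.31 times higher in every Drop-Seq library than in any 10X library, and IgM or IgD led at least 95.1% of Drop-Seq barcodes. With no IgA gene listed, that share rests on barcodes with enough IGHM or IGHD UMIs, not on a choice against IgA. Failed capture is not excluded, since both values assume that the methods capture IGHM alike. Between these methods, 1407 of 4398 genes differed over 2-fold. Failed capture was not tested for inDrop. A different mix of antibody clones in the cultures is a candidate explanation. Of the 44 genes higher in IgM or IgD barcodes within 10X, 36 had a positive log2 fold change in Drop-Seq against 10X (median of the 44 1.10). The 9 lower ones all had a negative one (median −1.57). The difference of 2.67 lay outside the 95% range of random gene sets matched on mean expression (−0.95 to 0.98). Those sets were not matched on length or GC content, which correlated with this fold change at 0.351 and −0.305. The different mix is a hypothesis, because the mix and the method coincide in these libraries.

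Mitochondrially encoded transcripts took 15.6% of UMIs in inDrop against 3.38% in Drop-Seq and 3.46% in 10X. A subset of damaged barcodes is excluded as the whole cause, since the median barcode of each inDrop library held at least 15.3%, above the 95% quantile of every other library (at most 6.39%). Another value argues against loss of cytosolic RNA with nuclear RNA kept as the whole cause. The 9 nuclear long noncoding RNAs had a median log2 fold change of 0.17 (SD 0.87) against Drop-Seq where mitochondrial genes had 2.00. It does not exclude such a loss, since it assumes that the methods capture these 9 RNAs alike, which was not tested. More reads per molecule in inDrop cannot be told apart from the method, since too few barcodes share a range. With 5 to 7 reads per UMI over the other genes, 33 and 46 inDrop barcodes held 27.8% and 16.3%. In Drop-Seq, 31, 746 and 25 such barcodes held 3.46%, 3.55% and 3.37%. With that range over all genes, 13 and 18 inDrop barcodes held 4.54% and 5.69%. That choice favours barcodes with few mitochondrial UMIs. In inDrop these UMIs had 12.3 and 12.6 reads each, against 9.28 and 8.905 for other genes. Also open, and not separated by these libraries, are the chemistry of each method, lysis of mitochondria and the state of the cultures.

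S phase and G2 and M phase genes were lower in inDrop than in Drop-Seq. Transcript length, GC content and abundance are excluded as the whole cause, since both list medians (−1.34 for S phase, −1.48 for the G2 and M phase genes with known length) lay at or below the 0.03 percentile of 10000 random lists matched on them. Fewer cycling cells among the barcodes of inDrop could not be separated from lower capture of these transcripts: the 99% quantile of G2 and M phase UMIs per thinned barcode was 0.886 of that in Drop-Seq on average (0.743 to 1.008 over library pairs) while the mean was 0.452 of it. The lowest pair fell below the bound of 0.75 set in advance and the others above it, and only 61.0% and 54.1% of inDrop barcodes reached the depth of the test.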

How the results depend on the processing

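Most results stayed near the main ones. Of 250 alternatives of the 20 results behind the comparisons, 201 (80.4%) counted as the same, 29 no longer passed, 4 passed where the main one did not, 15 moved and 1 reversed. For permutation tests, the same means an unchanged direction and side of the threshold. A count of genes or lists called was the same within 1.5-fold of the main count, whichever genes or lists it held. A correlation with length or GC content was the same if within 1 SD of the library pairs and of unchanged sign. Of 4219 alternatives of single genes, 4171 (98.9%) kept both their direction and their side of the threshold, 9 no longer passed, 26 newly passed and 13 reversed. Apart from the fixed genes, these were named for a large change in the main fit, which favours keeping both. Not filtering on low counts moved nothing, since all 4398 genes pass. Where a library left out leaves 1 of its method, it is assumed to vary like the others. Leaving out a Drop-Seq library leaves groups of 2, which cannot reach a p under 0.06667, and this accounts for most of the results that no longer passed. The genes called are limited by the inDrop tables, which list no gene under 25.2 and 26.5 CPM. Of the alternatives below, those on the read tables together, genes of at least 100 CPM, the shallower 50% of barcodes, barcodes led by IGHM or IGHD, inDrop against the other libraries together, no block on replicates 1 and 2, genes of all UMI tables, and reads for the length and GC trends were chosen after the data were seen.

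With each library left out in turn, the ratio of the methods that were highest and lowest with all libraries was 7.09 to 7.73 for UMIs per barcode, 3.21 to 3.25 for genes, 1.19 to 1.24 for genes at equal UMIs, 4.26 to 4.62 for reads per UMI, 4.69 to 5.02 for UMIs at equal reads, 4.51 to 4.68 for the mitochondrial share (inDrop over Drop-Seq, although without 10X replicate 1 the lowest was 10X at 3.19%), 1.23 to 1.34 for the ribosomal protein share and 1.57 to 1.83 for overdispersed genes. The difference in correlation within and between methods was 0.303 to 0.344. The genes called were 3421 to 3788 for inDrop against 10X, 3520 to 3788 for Drop-Seq against 10X and 3494 to 3769 for inDrop against Drop-Seq, and the called lists were 20 to 23. The lists that differed in variation were 0 to 11. The correlation with length was 0.437 to 0.461, 0.332 to 0.364 and 0.125 to 0.159 in that order of comparisons, and that with GC content −0.173 to −0.148, −0.315 to −0.288 and 0.0906 to 0.123.

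The ratio for the mitochondrial share was 6.55 with reads in place of UMIs, 4.57 for inDrop against the other libraries together, and 2.87 without barcodes under 1000 UMIs or over 15% mitochondrial, which removes high shares by design. The ratio of 10X to inDrop for the ribosomal protein share was 1.121 with that filter, which left Drop-Seq lowest, and 2.14 with reads. Over the genes that all UMI tables list, 9 lists differed in variation. With reads, the correlation with length was 0.427 for inDrop against 10X and 0.216 for inDrop against Drop-Seq, and that with GC content was −0.241 and −0.0447, the last reversed; the cause was not tested. Calls with reads correlated with the main log2 fold changes at 0.880, 0.979 and 0.855, and 228, 10 and 263 genes were called in the opposite direction. In the read tables together, 7212, 6773 and 7341 genes were called, since more genes were tested, and over genes of at least 100 CPM 1179, 1229 and 1189, since fewer were. That scaling moved all genes by 0.51, 0.01 and 0.50 log2. With an estimated correlation camera called 0 lists.

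For inDrop against 10X, with reads EEF1A1 was −0.52, CD79A −0.10 and IGHM −0.27, and over the genes of all read tables B2M was 0.021, EEF1A1 −0.43, CD79A −0.0088 and IGHM −0.18. With only barcodes led by IGHM or IGHD, B2M was 0.045 and IGHM −0.63, and IGHM was −0.085 for Drop-Seq against 10X, where the barcodes were chosen by that gene. Over genes of at least 100 CPM B2M was 0.067 and CD74 0.057, within the shift of all genes, and in the shallower 50% of barcodes CD79A was −0.59. For the others the cause was not tested.

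The replicate numbers do not pair the libraries, since no label ties them and same-numbered deviations correlated at −0.06, 0.04 and −0.16. A replicate block over replicates 1 and 2 called 3660, 3654 and 3674 genes and 22 lists, against 3671, 3682 and 3687 genes and 22 lists without the block on the same libraries.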

Other observations

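Within the 10X libraries, barcodes led by different heavy-chain classes differed in their other genes. These classes were chosen after the data were seen, and the values are given for both libraries without a test. Their CPM are without TMM and not on the scale of the comparisons between methods. Barcodes led by IgG, 48 and 202 of them, held 15230 and 16500 CPM of the kappa light chain IGKC, against 56.9 and 90.2 in those led by IgA. Those led by IgA, 1238 and 5132 of them, held 78960 and 81940 CPM of the lambda light chain IGLC2, against 18070 and 17940 in those led by IgG. Those led by IgM or IgD, 219 and 826 of them, held 50.9 and 64.0 CPM of the matrix protein SPARC and 76.4 and 86.0 of FEZ1, against 4.05 and 4.65 and 13.0 and 15.6 in those led by IgA. JCHAIN stood at 3248 and 3436 CPM in barcodes led by IgA and 849 and 983 in those led by IgM or IgD. The chemokine CCL22 stood at 135 and 149.7 CPM in barcodes led by IgA and 6.55 and 7.29 in those led by IgG. The median depth was 23820 and 22622 UMIs in barcodes led by IgA, 24444 and 27815 in those led by IgG and 29807 and 28166 in those led by IgM or IgD.

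Variable genes of antibodies also differed between the libraries. IGLV6-57 gave 2.41 UMIs per barcode in Drop-Seq (n = 3) and IGHV3-23 gave 3.24, and neither was listed in an inDrop UMI table. IGKC, at 31.7 UMIs per barcode in 10X (n = 2), was listed in no Drop-Seq UMI table. Of the 9790 genes, 1991 were listed in both 10X libraries only, 1982 in all Drop-Seq and 10X libraries but in no inDrop library, 71 in the Drop-Seq libraries only and 29 in the inDrop libraries only. Genes listed in inDrop and in no Drop-Seq UMI table included the amino acid genes SLC7A5 at 0.537 UMIs per barcode and CTH at 0.392, and the interferon-induced OAS3 at 0.379 (n = 2), each of which the Drop-Seq read tables listed.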
